A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

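Poly(A) RNA was sequenced from 12 cultures of Saccharomyces cerevisiae (YEF473A background per the labels): WT and H3i, each in YPGal and in YPD, with 3 biological replicates per group by the series design. Per the labels' protocols, RNA of replicates 1 and 2 was extracted with MagMax and made into libraries with TruSeq Stranded mRNA, and RNA of replicate 3 was extracted with Trizol and glass beads and made into libraries with TruSeq Stranded mRNA LT. The time H3i cells spent in YPD is not given in the sources used here.

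The deposited tables hold read counts per gene, which the authors made for each library. Per the submitters' processing notes, FastQC, HISAT2, SAMtools, Picard and DESeq2 were used with the sacCer3 genome build, without versions. The counting tool, and whether counting took account of the strand, are not given in the sources used here. Each table has 7127 features and 5 further entries that name no gene (such as reads that did not align). These entries held 27.5% to 38.6% of all counts in replicate 1, 66.3% to 74.5% in replicate 2 and 22.0% to 33.7% in replicate 3. They were left out of the gene totals and used as measures of library quality. Of the features 6047 carry a RefSeq locus tag, from which symbols, coordinates and lengths were taken.

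Counts were analysed in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood fit, TMM factors, filterByExpr) and limma 3.58.1. The planned model had the 4 groups and a term for the kit, on 12 libraries (6408 genes tested, 7 residual degrees of freedom). It gave a common biological coefficient of variation of 1.13. Because replicate 2 lacked counts for a large share of genes, a model without it was added after the data were seen (8 libraries, 6354 genes, 3 residual degrees of freedom, common coefficient 0.273). In that model the kit term is the same as a replicate block. The contrasts were YPD against YPGal in each strain, the difference of these responses (interaction), and H3i against WT in each medium. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The p-values measure the spread left among libraries of a group after the kit term. In the 12-library model that spread includes the loss of counts in replicate 2, so it is not the spread among cultures alone. Replicates 1 and 3 differ by more than counting error in every group. They also differ in kits and, in WT, in marker and mating-type genes.

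The comparisons, model, filters, gene lists and alternatives were fixed before the data were examined, except where the text says otherwise. The 34 gene lists cover histones and their chaperones, Rap1 and silencing factors, carbon sources, respiration, ribosomes, phosphate, mating, meiosis, stress, DNA damage, cell cycle, amino acid synthesis, marker genes, gene families near chromosome ends, and RNA classes and mitochondrial genes as measures of quality. They were tested with camera (inter-gene correlation 0.01), with camera with the correlation estimated from the data, and with fry. The fry PValue tests whether the genes of a list move on balance one way and its Mixed value whether they move in either direction; neither compares the list with other genes. Camera results are the ones reported. Members were also called with p-values adjusted over the list alone. Lists with under 3 tested genes were not tested.

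Genes named in the text are histone genes, RAP1, RIF1, RIF2 and SIR1 to SIR4, the 6 called genes with the highest and the 6 with the lowest fold change at 10 CPM or more, and up to 3 called genes per list with at least 3 called members. In the 8-library fit the rule was applied to replicates 1 and 3. Other genes are said to be chosen after their values were seen. Folds against a group at 0 were bounded with a floor of 3 counts over the group.

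The lowest and highest gene totals of each replicate number are given in the report. Levels under 1 CPM rest on at most 2 counts in replicate 1. Whether equal replicate numbers pair the libraries was checked by correlating deviations from the group means: the 18 pairs with the same number correlated at r = 0.351 to 0.794, and 12 of 12 libraries correlated best with libraries of their own number. A replicate block was among the alternatives fixed beforehand. The 12-library model, whose kit term holds replicates 1 and 2 together, does not take this pairing into account.

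The procedure was tested on simulated data with 100 genes changed 2-fold, 100 changed 4-fold and the ribosomal protein genes at −1 in H3i YPD. Each gene was drawn independently around its mean share over all libraries, without kit or replicate effects and without correlation between genes. The rates below test the code under that setting and need not hold for the real libraries. With the spread of the 12 libraries edgeR recovered 0 genes at 2-fold and 0 at 4-fold, with 0 of 6003 unchanged genes called; DESeq2 1.42.0 recovered 1 and 7, with 33 of 6071 called. With the spread of the 8 libraries edgeR recovered 9 at 2-fold and 80 at 4-fold, with 6 of 5910 called, and DESeq2 28 and 96, with 27 of 6017 called. With 12 libraries that had the spread of the 8, edgeR recovered 35 and 97. A list of ribosomal protein genes simulated at −1 was recovered at −1.02, −0.99 and −0.96 in the 3 settings.

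Alternatives fixed beforehand were RLE size factors, library totals, no filter, a filter at 10 CPM in 3 libraries, DESeq2, a replicate block, neither kit term nor block, replicates 1 and 2 only, only the groups compared, a 2-fold minimum and leaving out each library. Fits without the WT libraries of replicate 3 and with strain-by-replicate pairs as a block were added after seeing the data. Genes near chromosome ends were those with a midpoint within 20 kb of the end. Lists matched on level were drawn 10000 times from genes with known coordinates, in 20 bins of WT YPGal level; the restriction to genes with coordinates was made after an earlier version with a wider pool had been seen, in which the matched median was lower. Reads themselves, and so splicing, variants and strand, were not analysed here.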

Results

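RNA was sequenced from 12 cultures of budding yeast in 4 groups of 3 biological replicates. Wild type (WT) was compared with H3i, a strain that lacks HHT1, one of the paired genes for histone H3, and carries the other, HHT2, under the GAL1 promoter. That promoter is active in galactose medium (YPGal) and shut in glucose medium (YPD), so that YPD is meant to shut off the remaining H3 gene of H3i; H3 protein was not measured. Each strain was sampled in both media. Gene counts per library totalled 2176277 to 2525223 in replicate 1, 40950610 to 52278567 in replicate 2 and 8649749 to 11628815 in replicate 3. Levels are given in CPM, a gene's counts scaled to a gene total of 1e6.

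The 3 replicates were not alike. In replicate 2, 38.6% of the nuclear genes read at 50 CPM or more in the other replicates were at under 0.1 of that level, against 0.499% in replicate 1 set against replicate 3. By group the loss in replicate 2 was 46.0% in WT YPGal, 42.4% in WT YPD, 47.3% in H3i YPGal and 22.0% in H3i YPD. Comparisons with H3i YPD in the 12 libraries, and directions in replicate 2 given below, can therefore reflect this unequal loss. Between replicates 1 and 3 of a group, log CPM correlated across 5624 genes at r = 0.822 to 0.922, and between replicates 1 and 2 at r = 0.343 to 0.453; genes are not independent replicates. Results are therefore given from the planned fit of all 12 libraries (n = 3 per group) and from a fit of the 8 libraries of replicates 1 and 3 (n = 2 per group), which was chosen after seeing the data. Both WT libraries of replicate 3 also differed from the other WT libraries in marker and mating-type genes. HIS3 was read at 22.7 and 21.9 CPM there and had 0 counts in the other 10 libraries, while LEU2 and URA3 had 0 counts there and were read elsewhere. MF(ALPHA)1, which encodes the alpha pheromone, stood at 2460 and 2330 CPM in these WT libraries and at under 0.8 CPM in the other WT libraries. MFA1, for the a pheromone, stood at 1.97 and 1.30 CPM there and at 69.6 to 173 CPM in the other WT libraries. These genes were chosen after their values were seen. In the 8-library fit the n = 2 of WT in each medium is thus 1 library of each kind. The kit term is shared by both strains, so that it does not remove a difference found in WT alone.

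The state of the H3 genes was checked in every library. HHT1 (YBR010W, sacCer3 chromosome II, 256331 to 256741) was read in WT at 966 ± 328 CPM in YPGal and 691 ± 69.2 CPM in YPD (mean ± SD, n = 3). In H3i it stood at 3.34, 1.09 and 0.0997 CPM in YPGal (replicates 1, 2 and 3) and at 0, 2.66 and 0 CPM in YPD. Over replicates 1 and 3 together, WT was at least 2952-fold higher than H3i in YPD, with H3i set to a floor of 3 counts over the group. In replicate 2 it was 289-fold higher in YPD, with 109 counts in H3i. In YPGal WT was 1011-fold higher over replicates 1 and 3 and 1215-fold higher in replicate 2. HHT2 (YNL031C, chromosome XIV, 575640 to 576050) stood in H3i at 3444 ± 1057 CPM in YPGal and at 22.2 ± 7.80 CPM in YPD. The YPD level was 0.398%, 0.495% and 1.33% of the YPGal level in replicates 1, 2 and 3. In WT, HHT2 stood at 1049 ± 218 CPM in YPGal and 803 ± 27.6 CPM in YPD. The fall of HHT2 in H3i was called by edgeR in both fits (log2 fold change −7.64 ± 0.75 SE, adjusted p = 0.00152, 12 libraries; −7.42 ± 0.57, 8 libraries).

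**Figure D1:**
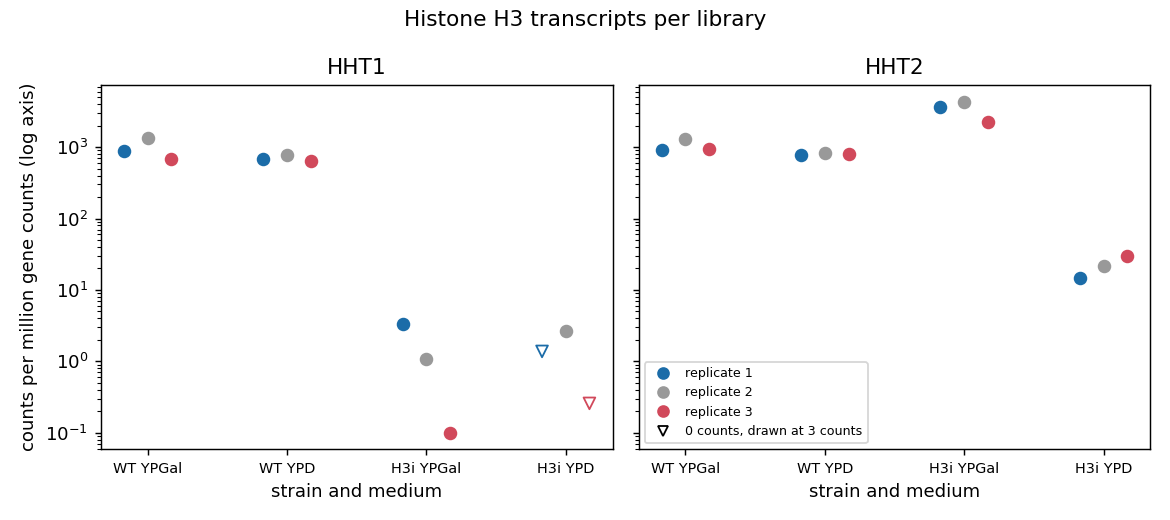
HHT1 (left) and HHT2 (right) in CPM on a log axis for the 4 strain and medium groups, 1 point per library, with open triangles for 0 counts drawn at 3 counts. HHT2 in H3i stands at 2284 to 4353 CPM in YPGal and at 14.7 to 30.3 CPM in YPD.

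The comparison of WT in YPD with WT in YPGal shows the medium's effect where H3 is made normally. The galactose genes fell: GAL2, the galactose transporter (−10.16 ± 1.01), GAL1, galactokinase (−9.25 ± 0.74), GAL10, the epimerase (−8.63 ± 0.63), and GAL7, the transferase (−8.31 ± 0.98; all n = 3). These 4 were the only calls of edgeR over all 12 libraries (0 higher, 4 lower of 6408 genes; 148 genes at an unadjusted p under 0.05; DESeq2 36, 4 of them higher). The fit of 8 libraries called 49 genes, 6 higher and 43 lower of 6354. The higher ones were the glucose transporters HXT1 (6.43 ± 0.35), HXT3 (5.93 ± 0.50) and HXT2 (3.09 ± 0.47), ARI1 (3.73 ± 0.55), and MIG2 (2.57 ± 0.37) and STD1 (1.98 ± 0.28), which act in glucose signalling. COX26, of the cytochrome c oxidase complex (−4.36 ± 0.26), and GCY1 (−4.90 ± 0.57) were among the lower ones. Of these 12 named genes 10 moved the same way in replicate 2; HXT1 (−1.56) and STD1 (−9.29) moved the other way there.

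By gene list, in the 12 libraries, the 9 galactose genes fell (median −6.16, camera adjusted p = 5.11e-33), as did 33 general stress genes (−1.91, 2.03e-11), and 78 ribosome biogenesis genes rose (0.89, 7.82e-08). These 3 calls held with an estimated correlation (adjusted p = 0.000996, 0.0483 and 0.0483). The calls of 7 further lists were lost with it. They were lower for glucose-repressed genes (median −3.59; adjusted p = 0.139 with an estimated correlation), the TCA cycle (−2.13; 0.0619), oxidative phosphorylation (−1.55; 0.0619), mitochondrial ribosomal proteins (−0.75; 0.472) and genes within 20 kb of a chromosome end (−0.57; 0.507). They were higher for cytosolic ribosomal proteins (0.71; adjusted p = 0.267) and Gcn4-controlled amino acid synthesis (0.53; 0.507). Members were called in the 8 libraries too: the galactose list had 7 of 9 members lower (9 adjusted over the list alone), general stress 5 of 33 (26), TCA cycle 1 of 16 (15), oxidative phosphorylation 0 of 34 (32) and the hexose transporters 3 of 14 higher (4).

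The count of 4 was 11 with a replicate block and 1 with strain-by-replicate pairs as a block. Without WT YPD replicate 2, GAL7 missed the threshold (adjusted p = 0.120). The count of 49 was 21 without WT YPGal replicate 1, 4 without WT YPD replicate 1, 381 without WT YPGal replicate 3 and 11 without WT YPD replicate 3, and 493 without both WT libraries of replicate 3. It was 654 by DESeq2 (305 higher, 349 lower), 444 with only the groups compared and 5 with neither kit term nor block; only HXT1, HXT3 and COX26 of 15 named genes kept their call whichever library was left out.

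H3i in YPD was compared with H3i in YPGal to show the shut-off of H3 together with the change of sugar. In the 12 libraries edgeR called 4 genes, all lower: HHT2, GAL2 (−7.82 ± 0.92), GAL1 (−7.42 ± 0.69) and GAL10 (−5.77 ± 0.56). Over the 8 libraries it called 2769 of 6354 genes, 1361 higher and 1408 lower, and 2180 of them changed at least 2-fold. Of 2729 of these genes that could be compared, 2024 (74.2%) moved the same way in replicate 2. That replicate lost 47.3% of genes in H3i YPGal and 22.0% in H3i YPD, so that a gene's direction there can come from the loss. The genes with the highest fold changes were LDS1, of the spore wall (9.44 ± 0.84), ANS1 (7.41 ± 0.50), THI5, of thiamine synthesis (7.37 ± 0.59), and PDC6, a pyruvate decarboxylase (7.34 ± 0.92), with RRT7 at 22.2 CPM in YPD against 0 counts in YPGal (adjusted p = 0.0611 without H3i YPGal replicate 3). MF(ALPHA)1 rose from 1.80 ± 1.96 to 79.5 ± 36.4 CPM (mean ± SD, n = 2), a call lost without H3i YPGal replicate 1 (adjusted p = 0.0876) or replicate 3 (0.388). The genes with the lowest were GAL2 (−7.29 ± 1.0), GAL1 (−6.69 ± 0.73), GAL10 (−5.48 ± 0.57), GAL7 (−5.03 ± 0.78), GCY1 (−3.96 ± 0.54) and RGI2 (−5.32 ± 1.85), the last of which lost its call without any 1 of the 4 H3i libraries (adjusted p 0.0510 to 0.311). All 12 moved the same way in replicate 2.

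Most ribosomal protein genes and genes of oxidative phosphorylation fell in H3i YPD. Of 137 cytosolic ribosomal protein genes 131 were lower and 0 higher (132 adjusted over the list alone), with RPS22B at −2.98 ± 0.33, RPS21A at −2.91 ± 0.34 and RPL43B at −2.75 ± 0.30 (8 libraries; many are paralog pairs that can share reads). All but 3 of 56 mitochondrial ribosomal protein genes fell (53; 54 adjusted over the list alone), as MRPL51 (−2.68 ± 0.48), and so did 33 of 34 nuclear genes of oxidative phosphorylation (34), as ATP15, of the ATP synthase (−3.49 ± 0.50), and COX12 (−3.33 ± 0.42). Of 16 TCA cycle genes 8 fell (8), as SDH2 (−3.36 ± 0.60), and of 78 ribosome biogenesis genes 39 (39), as CBF5 (−2.11 ± 0.33) and NOP58 (−1.97 ± 0.36). In the 12 libraries camera called ribosomal proteins (median −2.02, adjusted p = 1.03e-42; 0.0236 with an estimated correlation) and oxidative phosphorylation (−2.89, 6.96e-24; 0.00352 with an estimated correlation). Mitochondrial ribosomal proteins (−1.46), TCA cycle (−1.28) and ribosome biogenesis (−0.79) were called as well, and lost their calls with an estimated correlation (adjusted p = 0.102, 0.226 and 0.0612).

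The galactose genes fell in H3i, as 7 of 9 did in WT. All 9 galactose genes fell (median −4.79, camera adjusted p = 1.45e-16; 0.0145 with an estimated correlation; 9 of 9 members called in the 8 libraries and adjusted over the list alone). Among hexose transporters 10 of 14 rose (11 adjusted over the list alone), as HXT9 (6.58 ± 0.59), HXT1 (4.98 ± 0.33) and HXT3 (4.45 ± 0.46), and PDC5, a pyruvate decarboxylase, rose (5.30 ± 0.52) while HXK2, a hexokinase, fell (−1.91 ± 0.39; adjusted p = 0.0620 without H3i YPD replicate 1). The hexose transporter list was called in the 12 libraries (2.15, adjusted p = 0.0104), but not with a replicate block (adjusted p = 0.0782) or an estimated correlation (adjusted p = 0.347), and in WT its median was −1.52 (camera adjusted p = 0.487). SUC2, invertase, fell (−3.13 ± 0.64). The glucose-repressed list was not called (−0.21, camera adjusted p = 0.339), with 2 members higher and 4 lower (1 and 2 adjusted over the list alone).

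Most DNA damage genes rose in H3i YPD, and some heat shock and general stress genes. Of 24 DNA damage genes 15 rose and 0 fell (15 adjusted over the list alone), as HUG1, an inhibitor of ribonucleotide reductase (6.51 ± 0.67), RNR3, a subunit of that enzyme (4.64 ± 0.64), and RFX1 (2.51 ± 0.40). Of 25 heat shock genes 11 rose and 4 fell (13 and 4), as the chaperones SSA4 (5.0 ± 0.64), SSA3 (4.95 ± 0.75) and BTN2 (3.98 ± 0.33). Of 33 general stress genes 8 rose and 2 fell (6 and 2), as GND2 (4.29 ± 0.60). Camera called, in the 12 libraries, DNA damage (median 1.40, adjusted p = 0.010), heat shock (1.71, 0.00405) and general stress (0.89, 0.0273). With an estimated correlation none of the 3 held (adjusted p = 0.161, 0.226 and 0.438), and heat shock was not called with a replicate block (adjusted p = 0.0826). GIT1 (4.90 ± 0.42), a transporter controlled by phosphate supply, rose; the phosphate list (1.32, adjusted p = 0.0361; 5 of 16 members higher and 1 lower, 5 and 1 adjusted over the list alone) was not called with a replicate block (adjusted p = 0.146), an estimated correlation (0.481) or library totals (0.117).

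Most meiosis, PAU and flocculin genes rose in H3i YPD. Of 56 meiosis and sporulation genes 42 rose and 0 fell (50 adjusted over the list alone), as OSW1 (7.30 ± 0.81) and MEI5 (5.86 ± 0.88). The list called PAU genes throughout holds PAU, TIR and DAN genes, which encode cell wall proteins. Of its 25 tested genes 23 rose (23), as PAU19 (28.7 ± 2.92 CPM in YPD against 0 counts in YPGal). Members of the PAU family are alike in sequence. All 5 flocculin genes rose (5), as FLO11 (3.62 ± 0.25) and FLO1 (2.98 ± 0.35). Of 206 genes within 20 kb of a chromosome end 118 rose and 7 fell (122 and 8). By distance from the end, the share that rose was 53.3% within 10 kb, 60.3% at 10 to 20 kb, 35.8% at 20 to 30 kb and 18.6% beyond 100 kb. As lists, camera called in the 12 libraries meiosis (median 2.64, adjusted p = 4.32e-14), PAU genes (6.44, 3.55e-20), flocculins (2.95, 0.00129) and genes within 20 kb (2.03, 7.96e-16). With an estimated correlation flocculins lost the call (adjusted p = 0.0612) and the others kept it (adjusted p = 0.0238, 0.0187 and 0.0236). With the 5 PAU genes that had 0 counts in a group set to their bound, the PAU median in the 8 libraries was 5.65 in place of 5.82.

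**Figure D2:**
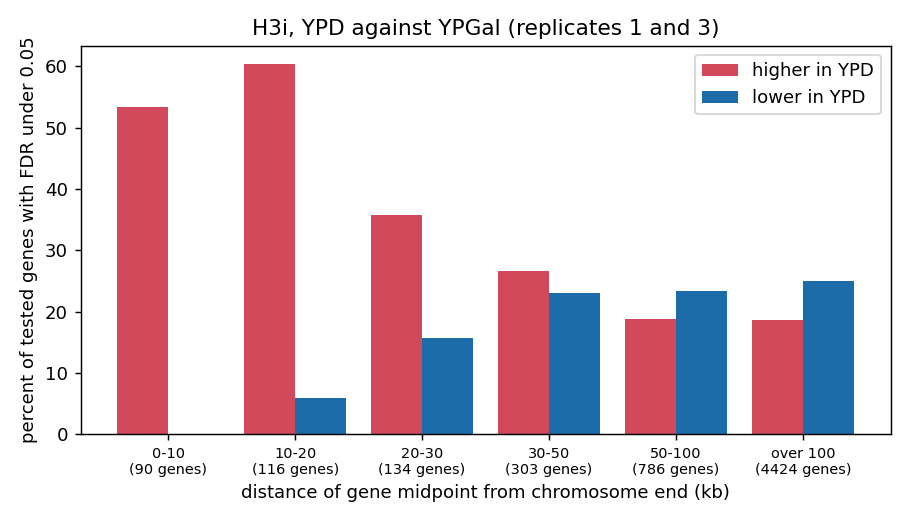
Percent of tested genes called higher (red) and lower (blue) in H3i in YPD against YPGal, by distance of the gene's midpoint from the chromosome end in kb (8 libraries). The share higher is 53.3% and 60.3% in the 2 bins within 20 kb and 18.6% beyond 100 kb.

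The direction of change followed the level of a gene. Of 359 genes at a mean of 500 CPM or more 243 fell and 16 rose (median −1.52), and of 466 genes at 1 to 5 CPM 163 rose and 1 fell (median 1.60). The 5th percentile of CPM per kb over 5109 coding genes was 23.3 and 27.0 in H3i YPD (replicates 1 and 3), 3.71 and 6.53 in H3i YPGal, and 1.31 to 5.70 in WT. Reads in no annotated feature went from 2.92% to 5.21% of all reads in replicate 1, from 2.25% to 2.61% in replicate 2 and from 5.01% to 7.34% in replicate 3 of H3i. Unaligned reads went from 61.3% to 51.9% in replicate 2 of H3i, so that the rise there need not hold among aligned reads. Counts in tRNA genes, as a share of gene counts, went from 0.0048%, 0.0046% and 0.0152% in H3i YPGal to 0.047%, 0.0431% and 0.0682% in H3i YPD (replicates 1, 2 and 3), against at most 0.0218% in WT. Lists of genes matched on WT YPGal level were drawn 10000 times, a comparison chosen after seeing the data. Meiosis genes (median 2.66 in the 8 libraries) lay above the matched lists' median of 1.23 and the upper limit of their central range, 1.76, PAU genes (5.82) above 2.28 and 3.35, and flocculins (2.86) above 0.54 and 1.69. COS genes (0.26) lay below the matched median of 0.97 (percentile 6) and telomere helicases (0.87) below 2.93 (percentile 1.4). Both are multicopy families, alignments to more than 1 place are not used, and only 4 of 8 helicase features were tested. DNA damage genes (1.25) lay above 0.22 and 0.73. Ribosomal proteins (−1.97) lay below the matched median of −1.12 and the lower limit of −1.32, and ribosome biogenesis (−0.79) at the 39.6th percentile of its matched lists. The TCA cycle fell less than the matched median (−1.31 against −1.60, percentile 84.4), and so did core histones (−0.89 against −1.55, percentile 94.2). With library totals in place of TMM, the median over all genes moved up by 0.40 in the 8 libraries, and 69.7% of calls were higher against 49.2%.

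Most genes of the M to G1 list fell. Of 25 genes of the M to G1 transition 15 fell and 2 rose (16 and 2 adjusted over the list alone), as AMN1, a regulator of mitotic exit (−2.73 ± 0.36), and RME1 (−2.31 ± 0.26). The list was called in the 12 libraries (median −1.42, camera adjusted p = 0.000374; 0.0236 with an estimated correlation). The mitotic cyclin CLB2 (−2.04 ± 0.26) and the G1 cyclin CLN1 (−2.24 ± 0.29) fell and the DNA polymerase gene POL2 rose (1.82 ± 0.26). The G1/S list (0.28, camera adjusted p = 0.789) and the G2/M list (median 0.28, mean −0.18, camera direction down, adjusted p = 0.244) were not called.

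Among histone and Rap1-related genes, in the 8 libraries, the H4 gene HHF2 (YNL030W, chromosome XIV, 576727 to 577038), which neighbours HHT2, fell (−1.50 ± 0.34) and so did the H2B gene HTB2 (−1.24 ± 0.28). HHF2 missed the threshold without H3i YPD replicate 1 (adjusted p = 0.0533) or H3i YPGal replicate 3 (0.0914), and HTB2 without H3i YPGal replicate 1 (0.0835) or H3i YPD replicate 1 (0.0697). Neither was called in the 12 libraries, except HTB2 with a replicate block (−1.22, adjusted p = 0.0254). RIF1, a Rap1-binding protein that limits telomere length, rose (1.34 ± 0.21), as did the silencing factors SIR4 (1.36 ± 0.25; adjusted p = 0.0652 without H3i YPGal replicate 3), SIR1 (1.09 ± 0.36) and SIR3 (0.90 ± 0.24). In replicate 2 HHF2 (0.43) and SIR3 (−1.60) moved the other way. SIR1 and SIR3 missed the threshold on leaving out 4 and 3 of the 4 H3i libraries (adjusted p up to 0.280 and 0.150). The change was −0.19 ± 0.23 for RAP1 (adjusted p = 0.520), 0.67 ± 0.39 for RIF2 (0.200) and 0.75 ± 0.28 for SIR2 (0.0593; called with RLE factors, 0.0465, and library totals, 0.0183); for RAP1 it was 0.21 with library totals. The core histone list holds HHT1 and HHT2, which the strain's construction sets, so that its test says little about other histones in any comparison with H3i. It was called in the 12 libraries (median −0.57, adjusted p = 0.000547), but not with an estimated correlation (adjusted p = 0.266), and 3 of 8 members fell in the 8 libraries (3 adjusted over the list alone).

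The 12-library count of 4 was 503 with a replicate block, 313 by DESeq2, 40 with library totals and 0 with replicates 1 and 2 alone (edgeR), and GAL2 missed the threshold without H3i YPD replicate 1 (adjusted p = 0.133) or 2 (0.112). The 8-library count of 2769 was 1285 without H3i YPGal replicate 1, 1201 without H3i YPGal replicate 3 and 1183 with neither kit term nor block, and none of its lists kept a call with an estimated correlation (lowest adjusted p = 0.249).

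The interaction tests whether H3i and WT respond differently to YPD, whichever of their differences is the reason. The WT libraries of replicate 3, which differ from replicate 1 in marker and mating-type genes, are among the 8 libraries. In the 12 libraries 1 gene was called, HHT2 (−7.31 ± 0.88, adjusted p = 0.0331). The 8 libraries gave 1756 genes, 835 with a higher and 921 with a lower response in H3i, and 1319 of 1750 (75.4%) went the same way in replicate 2. The highest were FDH1, formate dehydrogenase (10.12 ± 1.48), LDS1 (9.03 ± 1.32), ANS1 (8.28 ± 0.83) and DAL80, a regulator of nitrogen use (7.94 ± 1.79), with ERR3 and HSP32, which had 0 counts in WT YPD. Without WT YPGal replicate 3 the calls of LDS1 (log2 4.07, adjusted p = 0.975), DAL80 (3.29, 0.973) and ANS1 (6.75, 0.0712) ended, and that of DAL80 also without WT YPD replicate 3 (0.0788); ERR3 and HSP32 kept theirs under the omission of only 1 of the 8 libraries. The lowest were the ribosomal protein genes RPL12A (−3.63 ± 0.53), RPS21A (−3.56 ± 0.47), RPL8B (−3.55 ± 0.48), RPL16A (−3.44 ± 0.44) and RPL27B (−3.44 ± 0.47) and EGD2, of the nascent polypeptide complex (−3.43 ± 0.41). RPL16A and EGD2 went the other way in replicate 2.

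The response of 131 of 137 ribosomal protein genes was lower in H3i (132 adjusted over the list alone), and that of 54 of 78 ribosome biogenesis genes (66) and 22 of 56 mitochondrial ribosomal protein genes (23). It was higher for 21 of 33 general stress genes (27), 30 of 56 meiosis genes (39), 15 of 25 PAU genes (17), 5 of 5 flocculins (5), 10 of 24 DNA damage genes (12 higher and 2 lower) and 76 of 206 genes within 20 kb of an end (86, with 2 lower). Examples were RNR3 (5.40 ± 0.90), SSA4 (5.79 ± 0.82), GND2 (6.39 ± 0.87), FLO11 (4.26 ± 0.35) and CBF5 (−2.89 ± 0.46). In the 12 libraries camera called ribosomal proteins (median −2.84, adjusted p = 3.68e-59), ribosome biogenesis (−1.49), meiosis (3.03), general stress (3.23), the M to G1 list (−1.40), PAU genes (5.78), flocculins (3.58) and genes within 20 kb (2.67). These 8 held with an estimated correlation (adjusted p 0.0204 to 0.0319). Another 8 were lost with it: core histones (−0.36; adjusted p = 0.396), galactose (1.83; 0.264), glucose-repressed (3.84; 0.368), hexose transporters (2.19; 0.396), oxidative phosphorylation (−1.33; 0.0501), mitochondrial ribosomal proteins (−0.61; 0.600), phosphate (1.99; 0.580) and heat shock (1.37; 0.396). With a replicate block hexose transporters (adjusted p = 0.0751), phosphate (0.162) and heat shock (0.162) were not called, and phosphate not with library totals (0.110). DNA damage was not called (1.38, adjusted p = 0.0737), except with library totals (0.0459).

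**Figure D3:**
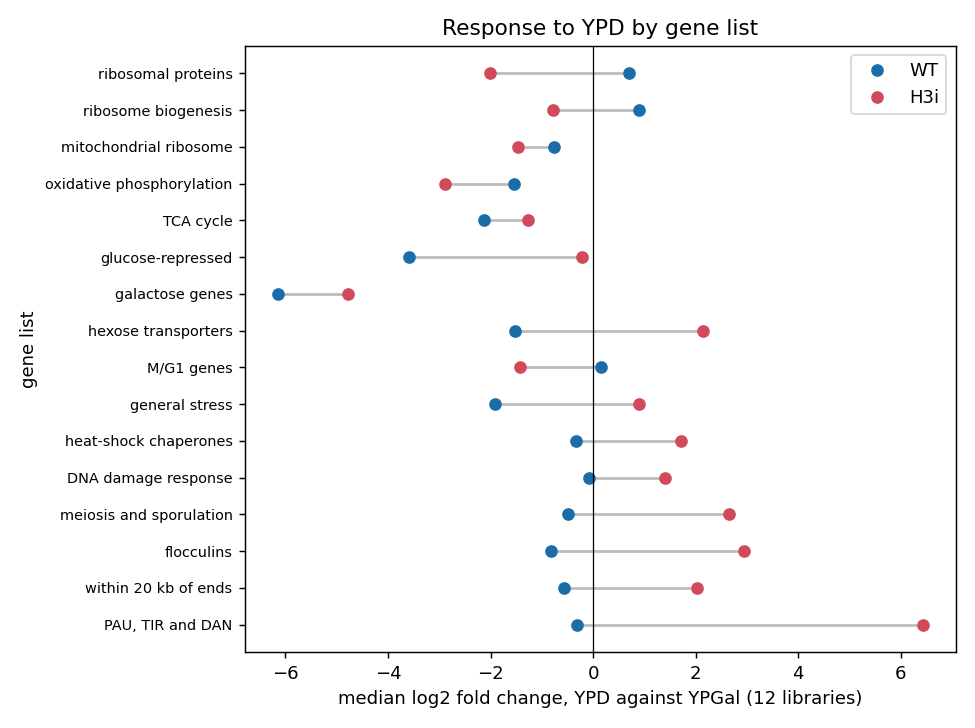
Median log2 fold change of YPD against YPGal for gene lists in WT (blue) and H3i (red), fit of 12 libraries. Ribosomal protein genes stand at 0.71 in WT and −2.02 in H3i, and general stress genes at −1.91 and 0.89.

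The interaction was positive for RIF1 (1.41 ± 0.30) and SIR4 (1.47 ± 0.35), which rose in H3i, and negative for HTB2 (−1.48 ± 0.39) and HHF2 (−1.51 ± 0.47), which fell in H3i and were at 0.24 and 0.02 in WT (8 libraries). RIF1 missed the threshold without WT YPD replicate 1 (adjusted p = 0.0580) or H3i YPGal replicate 3 (0.0857), and SIR4 without 4 of the 8 libraries (up to 0.106). HTB2 and HHF2 missed it without 6 libraries each (up to 0.128 and 0.171) and with library totals (0.0849 and 0.144). HHT2, the single gene of the 12-library fit, missed the threshold without any 1 of the 12 libraries (adjusted p 0.0873 to 0.436; log2 −7.95 to −6.91) and with RLE factors (0.130), while 208 genes were called with a replicate block, 0 with neither kit term nor block and 64 by DESeq2; 454 genes had an unadjusted p under 0.05. The count of 1756 was 623 without WT YPD replicate 1, 524 without H3i YPGal replicate 1 and 752 without H3i YPGal replicate 3, and 25 (24 higher, 1 lower) with neither kit term nor block. No list kept its call in the 8 libraries with an estimated correlation (lowest adjusted p = 0.375). With library totals the median over all genes moved up by 0.56 and 76.2% of the 8-library calls were higher against 47.6%.

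H3i and WT were compared in YPGal, where H3i makes H3 from the GAL1 promoter. HHF2 stood at 64.8 ± 60.2 CPM in H3i and 963 ± 298 CPM in WT (n = 3), a log2 fold change of −3.19 ± 0.36 in the 8 libraries that missed the threshold (adjusted p = 0.0603). HHT2 was at 1.67 ± 0.44 (adjusted p = 1). HHT1, which H3i lacks, was not called either (−10.13 ± 1.96, adjusted p = 1, 12 libraries; −9.68 ± 0.99, adjusted p = 0.0603, 8 libraries), so that a count of 0 says little here about differences between the strains. edgeR called 0 genes in both fits, with 17 at an unadjusted p under 0.05 in the 12 libraries and 114 in the 8, and DESeq2 called 2 and 12. Camera called 5 lists in the 12 libraries: core histones (median −0.15, mean −1.67), phosphate (−0.73), a-specific genes (1.94), alpha-specific genes (−1.48) and auxotrophic markers (0.48). None held with an estimated correlation (adjusted p = 0.541, 0.531, 0.405, 0.541 and 0.405). The a-specific, alpha-specific and marker lists hold genes in which WT YPGal replicate 3 differs from the other WT libraries. In the 8 libraries also without WT replicate 3 the medians of these lists were 0.51, 0.03 and 0.07. Core histones were not called with a replicate block (−0.09, adjusted p = 0.182), with which the galactose list was (0.55, adjusted p = 0.0425), as with library totals (0.0179) but not without either change (0.57, 0.0521). In the 8-library fit that also leaves out the WT libraries of replicate 3, chosen after seeing the data and with 1 WT library per medium, camera called glucose-repressed genes (−1.20, adjusted p = 8.05e-20), the TCA cycle (−0.59, 4.21e-07), oxidative phosphorylation (−0.45, 4.89e-08) and hexose transporters (−0.55, 0.000685) lower in H3i, and ribosome biogenesis higher (0.38, 2.35e-14); an estimated correlation was not run there. It also called phosphate (−0.68, 3.07e-07) and Rap1 and silencing factors (−0.30, 0.0251) lower, and a-specific genes (0.51, 0.000187), meiosis (0.55, 0.0251), other RNA classes (0.74, 0.0251) and genes within 20 kb (0.24, 0.0419) higher. Alpha-specific genes (0.03, 0.892) and core histones (0.11, 0.376) were not called in it.

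H3i and WT were compared in YPD to set cells with HHT2 shut beside cells with both H3 genes in glucose. Over the 12 libraries 6 genes were called. SSA4 (6.30 ± 0.96) and GAL10 (3.46 ± 0.50) were higher in H3i, and HHT2 (−5.66 ± 0.69), RPS3 (−3.58 ± 0.55) and RPS0B (−3.47 ± 0.53), of the small ribosomal subunit, and GAS1, a cell wall enzyme (−3.52 ± 0.51), were lower (n = 3). A total of 3163 genes were called in the 8 libraries, 1654 higher and 1509 lower, of which 2375 of 3119 (76.1%) went the same way in replicate 2. The highest were FDH1 (10.64 ± 1.06), DAL80 (9.23 ± 1.23) and GEX1, a glutathione exchanger (8.65 ± 1.01), with ERR3, RRT7 and HSP32 at 0 counts in WT. The lowest were RPS21A (−3.86 ± 0.36), RPL12A (−3.78 ± 0.40), RPL27B (−3.65 ± 0.36), RPS17B (−3.64 ± 0.39), RPS28B (−3.62 ± 0.54) and RPL8B (−3.61 ± 0.36). All 12 went the same way in replicate 2. The WT YPD libraries in the 8-library fit differ from each other in marker and mating-type genes.

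Lower in H3i were 132 of 137 ribosomal protein genes (133 adjusted over the list alone), 69 of 78 ribosome biogenesis genes (71), 26 of 34 oxidative phosphorylation genes (27) and 28 of 56 mitochondrial ribosomal protein genes (28). Higher were 31 of 33 general stress genes (32), 44 of 56 meiosis genes (47), 21 of 25 PAU genes (22), all 5 flocculins (5), 15 of 24 DNA damage genes (15, with 1 lower) and 131 of 206 genes within 20 kb (139, with 7 lower). HUG1 (6.22 ± 0.66), RNR3 (5.20 ± 0.67), GND2 (6.62 ± 0.69) and PAU5 (8.23 ± 0.68) were among them. Of 9 galactose genes 6 were higher in H3i (7 adjusted over the list alone), as GAL7 (3.62 ± 0.76). Camera called ribosomal proteins (median −2.87, adjusted p = 4.67e-68), ribosome biogenesis (−1.43), oxidative phosphorylation (−1.51), meiosis (3.20), general stress (3.11), the M to G1 list (−1.02), PAU genes (6.26), flocculins (3.66) and genes within 20 kb (2.80) in the 12 libraries. These 9 held with an estimated correlation (adjusted p 0.0131 to 0.0304). Core histones (−0.68; adjusted p = 0.189), galactose (2.69; 0.0947), glucose-repressed (3.42; 0.271), hexose transporters (2.17; 0.290), mitochondrial ribosomal proteins (−0.51; 0.582), heat shock (1.46; 0.422) and DNA damage (1.26; 0.260) were called and lost with it. Heat shock was not called with a replicate block (adjusted p = 0.183), RLE factors or library totals (0.0501 and 0.0580), and DNA damage not with RLE factors (0.0501). The median of mitochondrial ribosomal proteins was 0.01 with library totals, and their call was lost with RLE factors (0.0508).

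HHF2 was lower in H3i in YPD (−4.71 ± 0.39, 8 libraries; −5.35 ± 1.07, adjusted p = 0.0729, 12 libraries; −5.37, adjusted p = 0.0164, with a replicate block; 0.0400 with library totals). RIF1 was higher (1.25 ± 0.21), and RAP1 was at −0.57 ± 0.23 (adjusted p = 0.0692), a log2 fold change of 0.05 with library totals (adjusted p = 0.859). With a replicate block HTB2 (−1.11, adjusted p = 0.0267) and HHT1 (adjusted p = 0.0122; 0.0254 with library totals) were called in the 12 libraries as well. The 6 genes of the 12-library fit all missed the threshold on leaving out any 1 library of WT YPD or H3i YPD (adjusted p 0.0946 to 0.308) and with RLE factors (0.131 to 0.146). The count was 716 with a replicate block, 488 by DESeq2, 271 with library totals and 1 with either alternative filter, and 844 genes had an unadjusted p under 0.05. The 8-library count of 3163 was 1917 without WT YPD replicate 1 and 1579 with neither kit term nor block, and no list kept its call with an estimated correlation there (lowest adjusted p = 0.192). With library totals 77.3% of the 8-library calls were higher against 52.3%, with the median over all genes 0.60 higher.

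Across 6408 genes the log2 response to YPD in WT correlated with that in H3i at r = 0.0942 (12 libraries; genes are not independent, so no p is given). It was 0.0381 with a replicate block and 0.0969 in the 8 libraries. Leaving out H3i YPGal replicate 2 gave −0.0155, H3i YPGal replicate 1 0.156 and WT YPD replicate 3 0.0250 in the 12 libraries. In the 8 libraries leaving out WT YPD replicate 3 gave −0.190 and WT YPGal replicate 3 0.236. Of the 43 genes called lower in WT in the 8 libraries 21 were also called lower in H3i, against 9.53 if the calls were independent, and of the 6 called higher 5 were, against 1.29. Galactose genes were among those lower in both strains. GAL7 in YPD was at 3.22%, 5.16% and 5.87% of its YPGal level in H3i and at 0.0594%, 0.326% and 0.485% in WT (replicates 1, 2 and 3). GAL80 was at 40.1%, 146.8% and 86.3% in H3i and at 44.9%, 0.513% and 25.4% in WT, lower in H3i in replicate 1. The galactose list lost its call between strains in YPD with an estimated correlation (adjusted p = 0.0947).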

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

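The genes and lists in the next 2 paragraphs were singled out because a test of the difference between the strains' responses passed its threshold, and the alignments in the last paragraph because the comparisons do not use them. The paragraphs between weigh other patterns of the data. The tests on replicate 2, on WT replicate 3 and on ribosomal protein transcripts were chosen after the result was seen; those on the low level of genes near chromosome ends and on DNA, and the other splits of the libraries, were written before it.

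H3i and WT responded differently to YPD at 1 gene in the 12 libraries, HHT2 (−7.31), and at 1756 genes in the 8 libraries. Of those named by rule, FDH1 (10.12), LDS1 (9.03), ERR3 (8.20), ANS1 (8.28), HSP32 (8.07) and DAL80 (7.94) had a higher response in H3i, as did RIF1 (1.41) and SIR4 (1.47). HHT2 (−7.36), RPL12A (−3.63), RPS21A (−3.56), RPL8B (−3.55), RPL16A (−3.44), RPL27B (−3.44), EGD2 (−3.43), HHF2 (−1.51) and HTB2 (−1.48) had a lower one. ERR3 and HSP32 had 0 counts in WT YPD, so that their fitted values are no bound. Without WT YPGal replicate 3 the calls of LDS1, DAL80, ANS1, ERR3 and HSP32 ended (adjusted p = 0.975, 0.973, 0.0712, 1 and 1), with log2 values of 4.07, 3.29, 6.75, 4.35 and 4.43; DAL80 also lost its call without WT YPD replicate 3 (adjusted p = 0.0788), and ERR3 and HSP32 theirs under all but 1 of the 8 omissions.

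By list in the 12 libraries, the difference between the strains' responses had a median of 5.78 for PAU genes, 3.84 for glucose-repressed genes, 3.58 for flocculins, 3.23 for general stress, 3.03 for meiosis and 2.67 for genes within 20 kb of an end. It was 2.19 for hexose transporters, 1.99 for phosphate, 1.83 for galactose and 1.37 for heat shock. It was −2.84 for ribosomal proteins, −1.49 for ribosome biogenesis, −1.40 for the M to G1 list, −1.33 for oxidative phosphorylation, −0.61 for mitochondrial ribosomal proteins and −0.36 for core histones. With an estimated correlation 8 of these 16 lost the call: core histones (adjusted p = 0.396), galactose (0.264), glucose-repressed (0.368), hexose transporters (0.396), oxidative phosphorylation (0.0501), mitochondrial ribosomal proteins (0.600), phosphate (0.580) and heat shock (0.396). The core histone list holds HHT1 and HHT2, which the strain's construction sets.

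Other splits of the same libraries were fitted as well. For the interaction, 2 of 100 splits called as many genes as the real one (real 1, highest other 1), a share under 0.05 over splits that ignore the pairing of libraries by number. Among those that part as many pairs as the real one, the splits are too few for a share under 0.05. The 1 gene, HHT2, lost its call without any 1 of the 12 libraries, while its log2 value stayed between −7.95 and −6.91. For WT in YPD against YPGal 1 of 10 splits did (real 4, highest other 0), for H3i 1 of 10 (4 and 0), for the strains in YPD 1 of 10 (6 and 0) and for the strains in YPGal 10 of 10 (0 and 0; edgeR, 17 genes at an unadjusted p under 0.05, DESeq2 2). With 10 splits no share under 0.05 can be had. Among the splits that part as many replicate pairs as the real one, 3 others of each 10 and 17 others of the 100, the highest count was 0; the others part fewer pairs.

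Replicate 2 lost 38.6% of expressed genes: 46.0% in WT YPGal, 42.4% in WT YPD, 47.3% in H3i YPGal and 22.0% in H3i YPD. Its smallest gene total was 3.52 times the largest total of the other replicates, which argues against low depth. Replicate 1, made with the same kits, lost 0.499%, which argues against the kits. The share of genes lost differed between the coding strands of a chromosome by a median of 70.8 percentage points (42.1 in H3i YPD, 76.0 to 77.5 in the other groups). Between replicates 1 and 3 it was 0.0519, which could not be large where so few genes were lost. The plus strand lost more on 2 to 4 of 16 chromosomes, by group, which 1 fixed strand setting would not give. Of all reads in replicate 2, 51.9% to 61.3% did not align, against at most 7.36% in the other replicates. A counting step that follows the strand remains open as a candidate explanation. No biological explanation was tested.

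WT replicate 3 has HIS3 and TRP1 where the other libraries have 0 counts, and 0 counts of LEU2, LYS2 and URA3 against 11672 counts at the WT replicate 1 level. RNA with these 3 genes at the WT replicate 1 level may make up at most 0.0257% of these libraries. That argues against a mixture with RNA of the replicate 1 genotype, and does not show whether the libraries are WT. HHT1 was at most 0.0997 CPM in H3i replicate 3, which argues against a swap of WT and H3i within that replicate. Of 5 marker genes 4 were in the opposite state to WT replicates 1 and 2 in both media. LYS2 was not, because it stood at 0.828 CPM in WT YPGal replicate 2. It was low in H3i YPGal replicate 2 as well (0.915 CPM), and stood at 277 and 561 CPM in the WT and H3i YPD libraries of that replicate. The mating-type genes differ in the same libraries. These values argue against the same strain as in WT replicates 1 and 2. Which strain the libraries come from, and how it relates to the WT of the labels, is not settled.

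Genes within 20 kb of chromosome ends rose in H3i YPD (median 1.74 in the 8 libraries). Among 10000 lists matched on level they lay at percentile 100 (matched median 1.32, upper limit of their central range 1.59, highest 1.72). Another draw of 10000 in the same way, which is not a separate test, gave percentile 99.98. That argues against their low level as the whole cause only as far as 20 bins match it. The median change was 3.31 for genes at a mean under 1 CPM and 1.60 at 1 to 5 CPM. Differences in level inside a bin are therefore not excluded as a cause of the gap. Their median exceeded that of genes over 100 kb from the ends by 1.604 and 2.08 in replicates 3 and 1. A loss of ribosomal protein transcripts that raised all other genes alike would not by itself give this difference. The difference is the pattern itself, however, and the interior genes were not matched on level. Among genes under 5 CPM the gain in CPM per kb near the ends was 1.23 and 1.25 times that in the interior, as genomic DNA in these libraries could give. Counts in mitochondrial genes, as a share of gene counts, fell from H3i YPGal to H3i YPD. They went from 0.003%, 0.2034% and 0.0047% to 0.0018%, 0.0314% and 0.0007% (replicates 1, 2 and 3), and fell in WT as well. Added DNA that held mitochondrial DNA would by itself raise this share. Counts in tRNA genes did rise, and so did reads in no feature in replicates 1 and 3. In replicate 2 the unaligned share went from 61.3% in H3i YPGal to 51.9% in H3i YPD. The small rise of reads in no feature there, as a share of all reads, need not hold among aligned reads. DNA and the shut-off of H3 both stay open. In the reads counted, gene families did not move alike: COS genes (0.26) and telomere helicases (0.87) lay at percentiles 6 and 1.4 of their matched lists, PAU genes at 100. These are multicopy families, alignments to more than 1 place are not used, and only 4 of 8 helicase features were tested. Whether the helicases rose less than other genes is therefore not settled.

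Alignments to more than 1 place, which the comparisons do not use, were 21.2% of all reads on average in H3i YPD (23.5%, 18.5% and 21.5% in replicates 1, 2 and 3) and at most 14.9% in any other library. The cause was not tested.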

How the results depend on the processing

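Counts of called genes below are compared with 4 (WT YPD against YPGal), 4 (H3i YPD against YPGal), 1 (interaction), 0 (H3i against WT in YPGal) and 6 (in YPD) in the 12 libraries, and with 49, 2769, 1756, 0 and 3163 in the 8. Fits without replicate 2, without the WT libraries of replicate 3 and with pairs as a block, and all alternatives to the 8-library fit, were chosen after seeing the data. A group left with 1 library is assumed to vary like the others. The cause of each change was not tested.

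In the 12 libraries DESeq2 gave 36, 313, 64, 2 and 488. A replicate block gave 11, 503 and 208 for the WT, H3i and interaction counts and 716 for the strains in YPD, and strain-by-replicate pairs as a block gave 1, 160 and 0 for the first 3. With a replicate block r between the strains' responses was 0.0381. Beyond the calls the report gives with a replicate block, it changed no other call of a named gene or list. Without replicate 2 the counts were 49, 2769, 1756 and 3163. Library totals gave 40 in H3i and 271 between strains in YPD. RLE size factors gave 0 for the interaction and 0 between strains in YPD, as did neither kit term nor block (0 and 0), and replicates 1 and 2 only gave 0 in H3i, 0 for the interaction and 0 in YPD (edgeR throughout). With only the groups compared, without the WT libraries of replicate 3, no filter and the filter at 10 CPM, the strains in YPD gave 0, 0, 1 and 1, and the interaction without those WT libraries gave 0. Leaving out 1 library gave 3 to 5 for WT, 3 to 4 for H3i, 0 to 0 for the interaction, 0 to 0 in YPGal and 0 to 0 in YPD, and r from −0.0155 to 0.156.

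For the 8 libraries DESeq2 gave 654 in WT and 12 between strains in YPGal. With neither kit term nor block the counts were 5 in WT, 1183 in H3i, 25 for the interaction and 1579 between strains in YPD. With only the groups compared they were 444 in WT and 2 in YPGal, with no filter 3 in YPGal, and also without the WT libraries of replicate 3 493 in WT and 2 in YPGal. Leaving out 1 library gave 4 to 381 in WT, 1201 to 2118 in H3i, 524 to 1591 for the interaction, 0 to 1 in YPGal and 1917 to 2458 in YPD, and r from −0.190 to 0.236; also without the WT libraries of replicate 3 r was −0.0182. The 1 gene in YPGal came without H3i YPGal replicate 1.

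In 9 results, on 8 lists, the direction given by camera turned round between fits of which at least 1 called the list; the medians, given here, need not change sign with it. In YPGal the auxotrophic markers were at 0.01 without replicate 2. In the 8 libraries, also without the WT libraries of replicate 3, the other RNA classes were at 0 in WT YPD against YPGal and 0.74 between strains in YPGal, glucose-repressed genes at −1.20, hexose transporters at −0.55, the TCA cycle at −0.59 and ribosomal proteins at 0.053 in YPGal, and in YPD a-specific genes were at −0.96 and alpha-specific genes at 3.74.

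Of the other values of named genes in the 12 libraries 1407 stayed, 28 gained and 99 lost a call or size; of lists 1575, 32 and 87. These were, for the 8 libraries, 3490, 30 and 506 for genes and 986, 35 and 96 for lists. Of the genes named and called in the 8 libraries, 3 of 15 in WT, 59 of 84 in H3i, 30 of 76 for the interaction and 72 of 91 between strains in YPD kept their call whichever library was left out.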

Other observations

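Everything in this part was noticed after the data were seen, apart from the list tests, which were planned.

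The 4 alpha-specific genes were read at higher CPM in H3i YPD than in H3i YPGal in each replicate, though the list was not called. MF(ALPHA)1 in replicate 2 rested on 3 and 6 counts. The a-specific gene MFA1 was read in all H3i libraries at 76.8 to 133 CPM. MFA2 fell from 248, 191 and 474 CPM in H3i YPGal to 129, 24.2 and 304 CPM in H3i YPD (replicates 1, 2 and 3). BAR1 rose from 264, 352 and 175 to 476, 588 and 349 CPM, while STE2 and STE6 did not move alike in all replicates. STE3, the receptor for a-factor, went from 5.01, 1.03 and 18.4 CPM in H3i YPGal to 120, 35.5 and 165 CPM in H3i YPD (replicates 1, 2 and 3), SAG1 from 60.1, 2.43 and 54.3 to 388, 41.9 and 221 CPM, MF(ALPHA)2 from 10, 11.5 and 6.18 to 39.1, 40.8 and 54.6 CPM, and MF(ALPHA)1 from 0.417, 0.0669 and 3.19 to 53.8, 0.147 and 105 CPM. The list was not called in the 12 libraries (median 3.28, camera adjusted p = 0.0659; 0.0470 with RLE factors). In the 8 libraries 1 of 4 members, MF(ALPHA)1, was called higher (2 adjusted over the list alone). The a-specific list (−0.44, 0.789) and the silent mating loci (−2.78, 0.236) were not called. Of the 4 silent-locus features 3 were tested in the 12 libraries and 1 in the 8, too few for a list test. Alignments to more than 1 place are not used, so that reads shared with copies elsewhere would be missed. No conclusion on the silencing of these loci is drawn.

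Other lists were not called in H3i YPD against YPGal in the 12 libraries: variant and linker histones (median −2.07, camera adjusted p = 0.0659; 0.0394 with library totals), histone chaperones (0.54, 0.486; 8 of 20 higher and 1 lower in the 8 libraries, 8 and 1 adjusted over the list alone), Rap1 and silencing factors (0.81, 0.377; 4 of 13 higher, 3 adjusted over the list alone) and glycolysis (0.00, 0.976). Nor were haploid-specific genes (0.05, 0.483; 8 of 23 higher and 9 lower), Gcn4 targets (median −0.13, mean 0.23, 0.815), markers (0.97, 0.483), the telomere helicase family (0.62, 0.976), COS genes (0.84, 0.215) or other RNA classes (0.99, 0.150). The 9 genes of the mitochondrial genome were called lower (−2.81, 0.0166), but not with an estimated correlation (adjusted p = 0.546).

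Features with an open reading frame name and no RefSeq record rose more often than they fell in H3i YPD: 105 of 337 higher and 12 lower, median 1.11 (8 libraries). Some overlap other genes, and strandedness of counting is not stated.

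HHF2 was low in H3i in YPGal already, where HHT2 was high: 63.9, 5.13 and 126 CPM in H3i (replicates 1, 2 and 3) against at least 774 CPM in WT. HHF2 lies beside HHT2 in the reference genome, and reads can be shared with HHF1; how the GAL1 promoter was placed there was not analysed here.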
